A study of Mus musculus with 2 samples.

How the data were processed

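Poly-A RNA was measured in medullary thymic epithelial cells (mTEC) of B6 mice, sorted into a fraction with high and a fraction with low surface MHC class II. Per the labels' protocols, both fractions came from a pool of 3 mice. Per the series' design text, each library was made from about 100 ng of total RNA with a TruSeq kit that does not keep strand, was amplified with 15 PCR cycles and was read as 2 ends of 100 bases on a HiSeq2000. There was 1 library per group and 2 libraries in all.

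The submitters' processing notes name the mouse build mm9, CASAVA, Bowtie 1.0.0 and bedtools. Their settings, their order and the transcript annotation were not given in the sources used here. Per the file headers, the authors deposited for each RefSeq transcript a read count, a length in bases and an RPKM value. The deposited counts were whole numbers, and isoforms of a gene each held the reads they share. Every deposited RPKM value equalled the count divided by the length and by 1 read total per library, within 1e-06. That total was 213854095 for the MHC-II high and 142330178 for the MHC-II low library. The counts summed over transcripts came to 191391401 (89.5% of that total) and 74029717 (52.0%). Whether the mates of a pair were counted separately was not given in the sources used here.

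Both tables held lines that were not transcripts but stray read records, 18 in the high and 36 in the low table, and these were left out. The high table listed further genomic copies of a transcript on 840 separate lines, while the low table held 1 line per accession with the lengths of its copies added. Copies were therefore summed in the high table. Of 29920 accessions in either table, 29800 were in both with the same summed length and entered the analysis. Another 33 had different summed lengths and were left out. A run of 63 consecutive accessions (51 genes) was in the high table only, and a run of 24 (23 genes) was in the low table only. Both tables list other genes at 0 reads, so these missing lines were not read as 0. The plan had been to read them as 0. This departure was made once the tables had been seen, and the planned reading became an alternative.

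Gene symbols came from a RefSeq gene table of assembly GRCm38.p6 (29352 accessions) and from GENCODE vM21 (174), and 394 accessions had no symbol. The build differs from that of the authors, so the tables gave names and gene order only and no coordinates are given. Each gene was represented by its transcript with the most reads over both libraries. This gave 23411 genes with 138368543 reads in the high and 56077471 in the low library. Reads of near-identical gene copies can be split or counted on each copy. Among genes past the expression minimum, 255 had the same 2 read counts as another gene, and their values are uncertain. Without strand, reads of overlapping antisense genes cannot be told apart.

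CPM, read counts scaled to the library total, were computed from the deposited counts with TMM-scaled totals from edgeR 4.0.16 in R 4.3.3, 152834158 for the high and 50769789 for the low library. Genes with a mean CPM of at least 1 over both libraries were compared (17438 genes). The ratio of MHC-II high to MHC-II low was given an exact 95% Clopper-Pearson interval of the reads. A gene was counted as higher or lower when its whole interval lay beyond 2-fold. With 1 library per group there is no replicate check and no p-value across genes. The intervals compare these 2 libraries, and as PCR reads carry no molecular identifiers they cover counting error only. Where a gene had 0 reads, 3 reads stood as the limit, which is 0.0196 CPM in the high and 0.0591 CPM in the low library.

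For each of 32 gene lists the median log2 ratio over members past the minimum was set against 10000 random lists of the same size matched on mean expression in 20 bins. For lists with at least 6 such members, an order-statistic 95% interval of the median was given. For lists of tissue-restricted genes, reads were also summed over all members. Detection was compared after thinning the high library to the read total of the low one in 100 seeded draws. The named genes were the 10 with the highest lower limit and the 10 with the lowest upper limit of the ratio, leaving out gene models, clones, small RNA and pseudogenes. Also named were the 5 genes with the most reads in each library, Sirt1 to Sirt7 and Aire, and up to 4 members per list, 2 by reads and 2 by the size of the ratio. These rules, lists, thresholds and most alternatives were set before the data were examined.

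The comparison was tested on simulated data for the 23411 genes of the MHC-II high versus MHC-II low comparison, with 200 genes changed. It called 0 of 50 genes changed 1.5-fold, 49 of 50 changed 3-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold. It called 0 of 17189 unchanged genes, and 95.5% of the intervals held the true ratio. The simulated reads varied by counting error alone and were drawn from the same totals that the comparison used. The simulation therefore does not cover variation between libraries or mice, nor errors of scaling. Alternatives were DESeq2 1.42.0 size factors, upper quartile scaling, unscaled read totals, totals without the 20 most abundant genes of each library, other minimums and fold limits, halved reads, reads summed over transcripts and missing accessions as 0. The read totals behind the deposited RPKM, counting genes with identical reads once, and thinning to the TMM-scaled total were added after the data had been seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.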

Results

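Medullary thymic epithelial cells (mTEC) display tissue antigens to developing T cells, and surface MHC class II separates their more mature from their less mature fraction. The series title names Sirt1, a deacetylase, in the tolerance that the transcription regulator Aire brings about. Transcript counts were compared between 1 library of MHC-II high and 1 library of MHC-II low mTEC, sorted from a pool of 3 mice. The high library held 138368543 reads on 23411 genes and the low library 56077471. No group had a second library, so each difference below is between these 2 libraries. For single genes and summed reads its 95% interval covers counting error only. The interval of a list median instead reflects the spread of ratios among the list's genes.

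The first question was which genes differ between the fractions. Aire was 27.1-fold higher in the MHC-II high library (interval 25.5 to 28.8), with 571 against 21.0 CPM. The other genes with the highest lower limits included several known from peripheral tissues. Dcaf12l2 was 69.3-fold higher (48.2 to 104), the neuropeptide gene Adcyap1 54.9-fold (30.6 to 110) and the enamel organ gene Amtn 51.9-fold (28.2 to 108). The estrogen sulfotransferase Sult1e1 had 828 reads against 1, a ratio of 275 with limits of 49.2 and 10877. The beta-defensin Defb19 was 52.6-fold higher, the cytokine gene Iltifb 82.5-fold on 2 reads in the low library, Ripply2 41.1-fold, and the epididymal gene Crisp1 37.4-fold. Pate14 was 33.5-fold higher.

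In the other direction, the endothelial sialomucin Emcn was 122-fold higher in the MHC-II low library (interval 74.7 to 215), on 16 against 650 reads. Globin genes followed, with Hbb-bs 56.4-fold higher there (54.0 to 59.0), Hbb-b2 and Hbb-bt 48.3-fold and Hba-a1 and Hba-a2 40.9-fold. Hbb-b2 and Hbb-bt held the same reads, as did Hba-a1 and Hba-a2, so members of each pair cannot be told apart. Mgp, a matrix protein of the vessel wall and cartilage, was 39.1-fold higher in the low library, Ctla2a 40.6-fold, Duxf3 42.3-fold and Btbd35f21 63.7-fold. The last 2 genes belong to multicopy families, and their reads are uncertain.

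Among 17438 genes past the minimum, 2530 were higher and 1907 lower in the MHC-II high library beyond 2-fold, so 57.0% of these genes were higher. This split depends on the scaling. With unscaled read totals, which move the median log2 ratio of all genes by 0.29, it was 3453 to 1282 (72.9% higher), and with the read totals behind the deposited RPKM, which move it by 1.01, it was 7232 to 471 (93.9%). Without an expression minimum it was 2837 to 3822 (42.6%).

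Among the most abundant genes of the high library were Cd74, the invariant chain of MHC class II (9289 CPM), Fcgbp (5863 CPM) and B2m (5581 CPM), with NR_046233, an accession with no symbol, at 6143 CPM. In the low library NR_046233 came first, with 7.08% of the reads against 0.679% in the high library. The mitochondrial leucyl-tRNA synthetase gene Lars2 held 2.12% against 0.0941%. Which RNA the reads on NR_046233 and Lars2 come from was not tested. The chemokine genes Ccl21b, Ccl21c and Ccl21d, whose reads were identical, followed at 8404 CPM. The 10 most abundant genes held 15.2% of the reads in the low and 5.91% in the high library. In the low library 5 of these 10, Ccl21b, Ccl21c and Ccl21d among them, had identical reads. Its share may therefore count the same reads more than once and be too high.

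**Figure D1:**
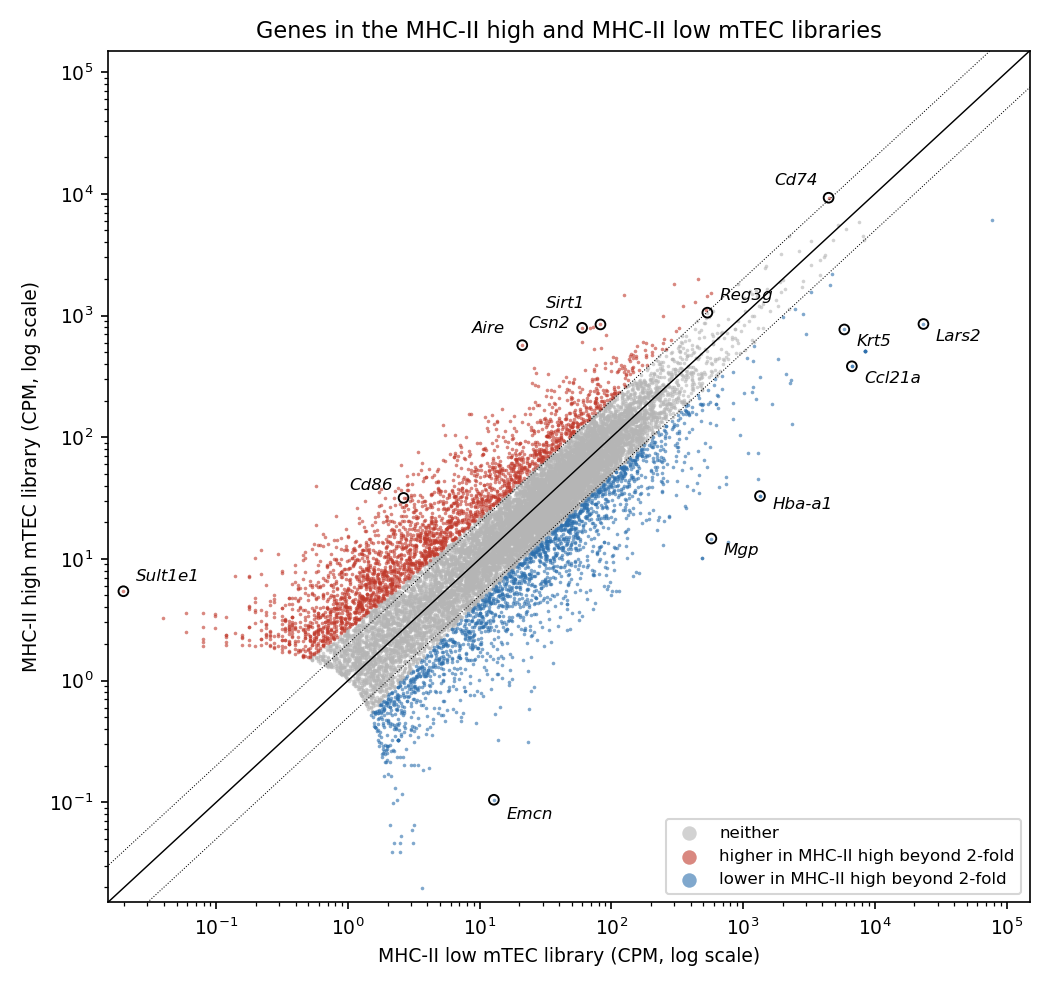
Each point is a gene past the expression minimum with reads in both libraries, with its CPM in the MHC-II low library on the x axis and in the MHC-II high library on the y axis, both on log scales; the solid line marks equal values and the dotted lines 2-fold. Red points are the 2530 genes higher and blue points the 1907 genes lower in the high library beyond 2-fold (genes with 0 reads in 1 library are not drawn), and Sirt1 lies at 845 against 82.5 CPM.

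Sirt1, the subject of the series title, was 10.2-fold higher in the MHC-II high library (interval 9.92 to 10.6), with 129089 reads or 845 CPM against 4190 reads or 82.5 CPM. No other sirtuin was beyond 2-fold by its whole interval. The mitochondrial deacetylase Sirt3 had a log2 ratio of −1.11, Sirt5 −0.57, Sirt2 −0.49, Sirt7 −0.37, Sirt6 −0.02 and Sirt4 0.52. The signs of Sirt2, Sirt5, Sirt6 and Sirt7 changed with the RPKM read totals, and that of Sirt6 also with other scalings. Both listed Sirt1 transcripts, which share reads, gave log2 ratios of 3.36. The genes on either side of Sirt1 were near equal in the libraries, with log2 ratios of 0.41 for Herc4 and 0.04 for Dnajc12. In the deposited RPKM, Sirt1 was at 154.5 against 7.53, a 20.5-fold ratio.

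Of 11 classical histone deacetylase genes, Hdac9 was 4.07-fold higher in the MHC-II high library (interval 3.74 to 4.43) and Hdac11 was 2.58-fold higher in the low one (2.48 to 2.69). The other 9 were within 2-fold or had intervals that reached it. Hdac2, with the most reads, had a log2 ratio of 0.63 and Hdac3 one of −0.63. The list's median was −0.63 (interval −0.90 to 0.63), at the 1.83 percentile of random lists, and 0.38 with the RPKM read totals.

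**Figure D2:**
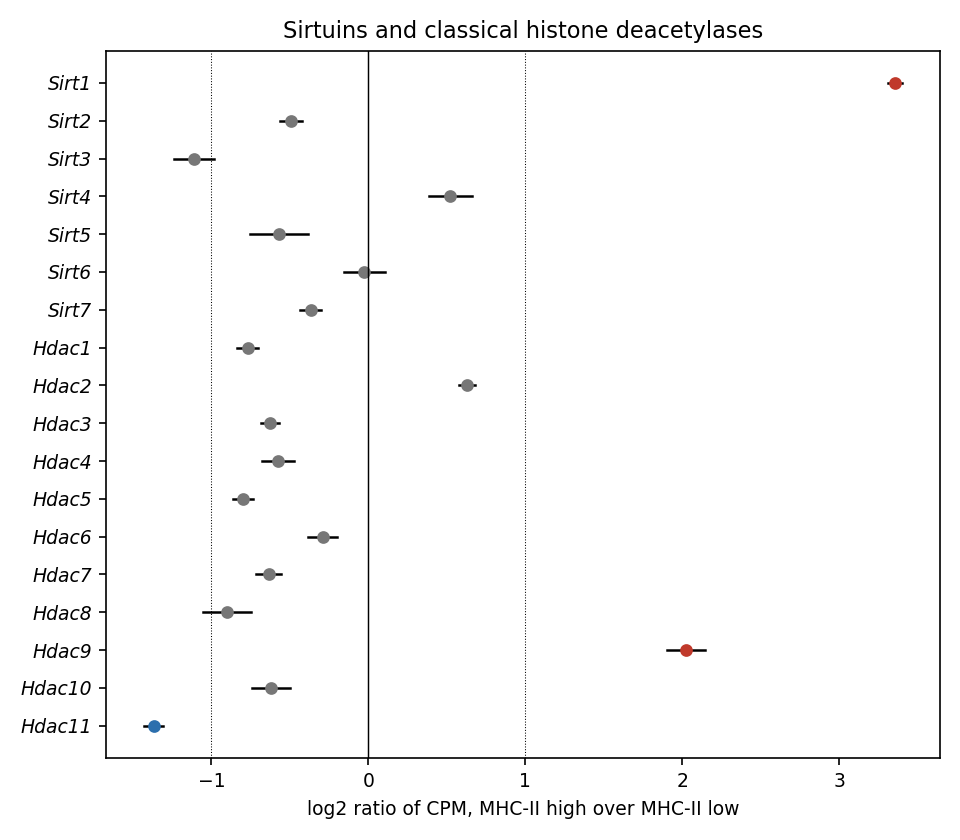
The x axis is the log2 ratio of CPM in the MHC-II high over the MHC-II low library for 7 sirtuin and 11 classical histone deacetylase genes on the y axis; points are the ratios, lines the exact 95% counting intervals and dotted lines mark 2-fold. Sirt1 (3.36) and Hdac9 (2.02) are higher and Hdac11 (−1.37) is lower beyond 2-fold.

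Genes of mature mTEC were higher in the MHC-II high library, where 9 of 10 listed genes passed 2-fold and none was lower. Besides Aire, the transcription factor gene Fezf2 was 3.03-fold higher (interval 2.96 to 3.10) and the costimulatory ligand gene Cd86 was at 31.7 against 2.64 CPM (limits of the ratio 10.1 and 14.4). The list's median log2 ratio was 2.21 (1.33 to 3.59), above all 10000 random lists. The MHC class II genes are a check of the sort, since the gate used their product. Of 10, 5 were higher beyond 2-fold, Cd74 2.09-fold, H2-Oa 3.18-fold and H2-Ob 5.99-fold, and the median was 1.03 (0.34 to 1.67). H2-Aa, at 4485 against 2240 CPM, was 2.00-fold higher. Others differed less, and of these, picked after their values were seen, H2-Eb1 was 1.64-fold and H2-Ab1 1.26-fold higher, and H2-DMa had a log2 ratio of −0.06 that turned positive with unscaled and RPKM read totals. The dendritic cell and macrophage list, given further on, was also higher in this library.

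Genes of immature, CCL21-producing and basal mTEC went the other way, with 9 of 11 lower in the MHC-II high library, 0 higher and a median of −2.35 (interval −4.05 to −0.57). The T cell attractant gene Ccl21a was 17.5-fold higher in the low library and Ccl21b 16.6-fold, with reads shared among the Ccl21 copies. The basal keratin genes Krt5 and Krt14, picked after their values were seen, were 7.63-fold and 7.86-fold higher there. Genes of tuft-like cells, a chemosensory type of the medulla, were lower in the high library in 9 of 11 cases, with a median of −1.56 (−2.12 to −0.57). With the RPKM read totals 3 of 11 were lower and the median was −0.55. The cytokine gene Il25 was 5.67-fold, Gng13 4.34-fold, Avil 4.32-fold and the channel gene Trpm5 3.49-fold higher in the low library. Endothelial, fibroblast and erythroid genes, given further on, were higher in the same library.

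The remaining epithelial lists were mixed. Of 9 cornified-cell genes, which follow Aire expression in the mTEC lineage, Sprr1b was 2.74-fold higher in the high library and 0 were lower, and the median was 0.19 (−0.78 to 0.49, 76.9 percentile). Krt10 and Spink5, with the most reads, had log2 ratios of −0.28 and 0.32, and Krt1 had one of −0.91; the signs of Krt1 and Krt10 changed with the RPKM read totals, and that of Krt10 also with unscaled totals. Cortical epithelial genes split, with Tbata 4.76-fold and the chemokine gene Ccl25 6.79-fold higher in the high library, and the protease gene Ctsl 6.10-fold and Cxcl12 13.0-fold higher in the low one. The median of that list was 0.56 (−2.61 to 2.25, 96.4 percentile). Among genes of all thymic epithelium, the regulator gene Foxn1 was 3.24-fold higher in the high and Krt17 2.58-fold higher in the low library. Krt8 was at 1569 against 1955 CPM. This median was within 0.01 of 0, and its sign changed with the scaling.

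Cell cycle genes were higher in the MHC-II high library, with 10 of 16 beyond 2-fold, 0 lower and a median of 2.00 (interval 0.64 to 2.22), above all random lists. Cdk1, the kinase that drives mitosis, was 6.05-fold higher, the proliferation marker gene Mki67 4.15-fold and the topoisomerase gene Top2a 5.96-fold. The replication clamp gene Pcna was 1.70-fold higher. Of 17 NF-kB and TNF receptor family genes, 2 of which are also in another list, 7 were higher and 0 lower, with a median of 0.97 (0.22 to 1.42). Tnfrsf11b, the decoy receptor for RANKL, was 4.55-fold higher, Rel 4.50-fold and the inhibitor gene Nfkbia 2.67-fold, and Nfkb2 had a log2 ratio of 0.78. Among 12 chemokine genes, 5 of which are also in another list, 6 were higher and 2 lower. Their median was 1.28 (−0.52 to 2.45, 99.99 percentile), but reads summed over the list were lower, with a log2 ratio of −1.61. Xcl1, which attracts dendritic cells, was 39.8-fold higher (20.9 to 87.2) on 1077 against 9 reads, and Cxcl10 was 1.83-fold higher. Dendritic cell and macrophage genes, given further on, were higher in the same library, with a median of 1.65.

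Interferon-stimulated genes were lower in the MHC-II high library in 8 of 14 cases and higher in 0, with a median of −1.09 (interval −2.50 to 0.25, 0.02 percentile). With the RPKM read totals 4 were lower and 3 higher, with a median of −0.08, and with unscaled totals 6 were lower and 1 higher. Ifit3 was 13.3-fold higher in the low library (12.9 to 13.7), the regulator gene Irf7 6.78-fold and Oasl2 2.03-fold, while Irf1 had a log2 ratio of 0.25. Endothelial (−3.71), fibroblast (−3.04) and erythroid (−5.35) genes had negative medians as well. Of 17 Aire partner and elongation genes, Top2a was higher and the Ku80 gene Xrcc5 was 2.55-fold higher in the low library. The topoisomerase gene Top1 and the acetyltransferase gene Ep300 had log2 ratios of 0.61 and 0.40, and the median was 0.06. No gene of 12 for MHC class I and the immunoproteasome passed 2-fold, while 4 were higher with the RPKM read totals. B2m and H2-K1 had log2 ratios of 0.10 and −0.22, and Psmb9 and Tap1 were 1.99-fold and 1.76-fold higher in the low library. The median was −0.23 and turned positive with unscaled and RPKM read totals.

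Genes of the immediate early and heat shock response were abundant in both libraries. The chaperone gene Hspa1a was at 4193 CPM in the high and 8202 CPM in the low library and Hspa1b at 4515 and 8133 CPM. Of 11 such genes, Jun was 2.17-fold higher in the low library and 0 were higher in the high one, and Dusp1 was at 606 against 1209 CPM. With unscaled totals 0 were lower, and with the RPKM read totals 0 were lower and 1 higher. The median was −0.81 (1.49 percentile), and 0.19 with the RPKM read totals. Negative medians were also found for endothelial (−3.71), fibroblast (−3.04) and erythroid (−5.35) genes, given further on.

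The next question was whether genes restricted to peripheral tissues, many of them induced by Aire, differ between the fractions. Over 8 lists pooled, 34 of 72 genes past the minimum were higher in the MHC-II high library and 4 lower. Their median log2 ratio was 1.03 (interval 0.63 to 1.60), above all 10000 random lists, 95% of which had medians of −0.23 to 0.34. Some of the 34 higher genes, such as Csn1s1, Csn3, Ldhc and Ddx4, passed the minimum only through the high library. The random lists were drawn under the same minimum. Reads summed over the pooled lists were 1.97-fold higher (1.96 to 1.99), a log2 ratio of 0.98 that was 0.43 without Reg3g, Csn2 and Syt1. As given further on, dendritic cell and macrophage genes were also higher in this library (median 1.65), and endothelial (−3.71) and fibroblast (−3.04) genes lower. The genes listed as Aire-induced are no separate set, as 9 of them are also in another list. Of these Aire-induced genes, 6 of 10 past the minimum were higher and 1 lower, with a median of 1.80 (−0.83 to 3.73, 99.99 percentile). The milk casein gene Csn2 was 13.2-fold higher (12.8 to 13.7), with 792 against 59.9 CPM, and the neuronal gene Pcp4 21.2-fold (17.2 to 26.4). Wfdc18 had a log2 ratio of −0.83. Without Csn2, the summed log2 ratio of this list turned from 0.92 to −0.34. The 2 genes listed as Aire-independent went in opposite directions, Gad1 being 5.35-fold higher in the high and Crp 3.94-fold higher in the low library, with a summed log2 ratio of −0.95.

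By tissue, intestinal genes were higher in 7 of 11 cases and lower in 0, with a median of 2.06 (interval 0.53 to 2.71). The brush border genes Alpi and Sis were 8.66-fold and 6.56-fold higher, Cdh17 4.17-fold, and the antimicrobial lectin gene Reg3g had 1055 against 535 CPM. Mammary and salivary genes had a median of 2.74 (−1.19 to 3.73), 4 of 7 being higher and 0 lower, with Csn1s1 10.8-fold higher. Their summed log2 ratio of 0.83 turned to −0.76 without Csn2. Liver genes had a median of 1.40 (−0.36 to 2.93), with 7 of 12 higher, among them Alb 11.0-fold, Fgb 9.58-fold, Apob 7.61-fold and Apoa1 3.03-fold, and Crp lower. Pancreatic genes had a median of 1.38 (−0.02 to 3.13), with 6 of 11 higher and 0 lower. The hormone gene Ppy was 12.7-fold and the protease gene Ctrb1 8.76-fold higher, while Iapp was at 62.9 and 63.9 CPM. Testis genes had a median of 1.72 (97.7 percentile), with 4 of 5 higher and 0 lower, among them Fabp9 4.64-fold, Ldhc 4.37-fold and Tnp2 3.30-fold. Ldhc and Ddx4 passed the minimum only through the high library, being at 0.591 and 0.748 CPM in the low one. Csn1s1 and Csn3 of the mammary and salivary list did so too, at 0.591 and 0.827 CPM there. Reads summed over all 10 testis genes gave a log2 ratio of 1.99 (1.89 to 2.09).

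The lists of 3 other tissues lay within the central 95% of random lists. Of nervous system genes, 2 of 9 were higher and 0 lower, with a median of 0.65 (interval 0.55 to 1.74, 91.5 percentile), Syt1 3.34-fold and Gad1 higher and Mbp at a log2 ratio of 0.82. Of striated muscle genes, 2 of 10 were higher and 1 lower, with a median of 0.49 (−1.16 to 1.38, 84.3 percentile). Myh4 was 13.1-fold and Actn3 2.60-fold higher, and the titin gene Ttn had a log2 ratio of 0.52. Of eye genes, 2 of 7 were higher and 2 lower, with a median of 0.30 (−2.49 to 2.83, 63.2 percentile). The lens crystallin gene Cryaa was 7.13-fold and Gnat1 2.65-fold higher in the high library, and the cone opsin gene Opn1sw was 5.63-fold higher in the low one. The summed log2 ratio of the eye list was 1.24, and −0.08 without Cryaa.

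Markers of cells other than epithelium differed between the libraries too. All 8 endothelial genes were lower in the MHC-II high library, with a median of −3.71 (interval −6.93 to −1.22). Besides Emcn, Pecam1 was 21.4-fold higher in the low library, at 163 CPM, and the clotting factor gene Vwf 4.35-fold, at 142 CPM. Of 7 fibroblast genes 5 were lower and 0 higher, with a median of −3.04 (−3.47 to 0.81). The matrix gene Dcn was 9.34-fold higher in the low library, at 535 CPM, Lum 11.1-fold and Pdgfra 9.60-fold, and Col3a1 was at 208 against 25.4 CPM. Col1a1 had a log2 ratio of −0.68 that turned positive with the RPKM read totals. With unscaled or RPKM read totals, 1 fibroblast gene was higher in the high library and 5 were lower. Of 4 erythroid genes, 3 globin genes were lower, with a median of −5.35.

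Dendritic cell and macrophage genes were higher in the MHC-II high library in 6 of 10 cases and lower in 0, with a median of 1.65 (interval −0.74 to 2.36, 99.9 percentile). The lysozyme gene Lyz2 was 4.89-fold higher, at 362 CPM, the mannose receptor gene Mrc1 6.17-fold and Flt3 5.12-fold. In contrast, Clec9a, Itgax and Ptprc had log2 ratios of −0.97, −0.74 and −0.52, which turned positive with the RPKM read totals. Of 5 B cell genes, 3 were higher and 0 lower, with a median of 1.39 (94.0 percentile). Ms4a1 was 6.92-fold and Blk 6.10-fold higher, while Cd79b had a log2 ratio of −0.02. Ms4a1 passed the minimum only through the high library, at 3.81 against 0.552 CPM. Thymocyte and T cell genes were low in both libraries, with 1 of 13 higher and 2 lower in the high library and a median of −0.89 (−1.13 to 0.03, 0.29 percentile), which was 0.11 with the RPKM read totals. Cd8b1 was 3.52-fold and Rag1 3.20-fold higher in the low library, and Lck and Bcl11b had log2 ratios of −0.63 and −0.44.

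**Figure D3:**
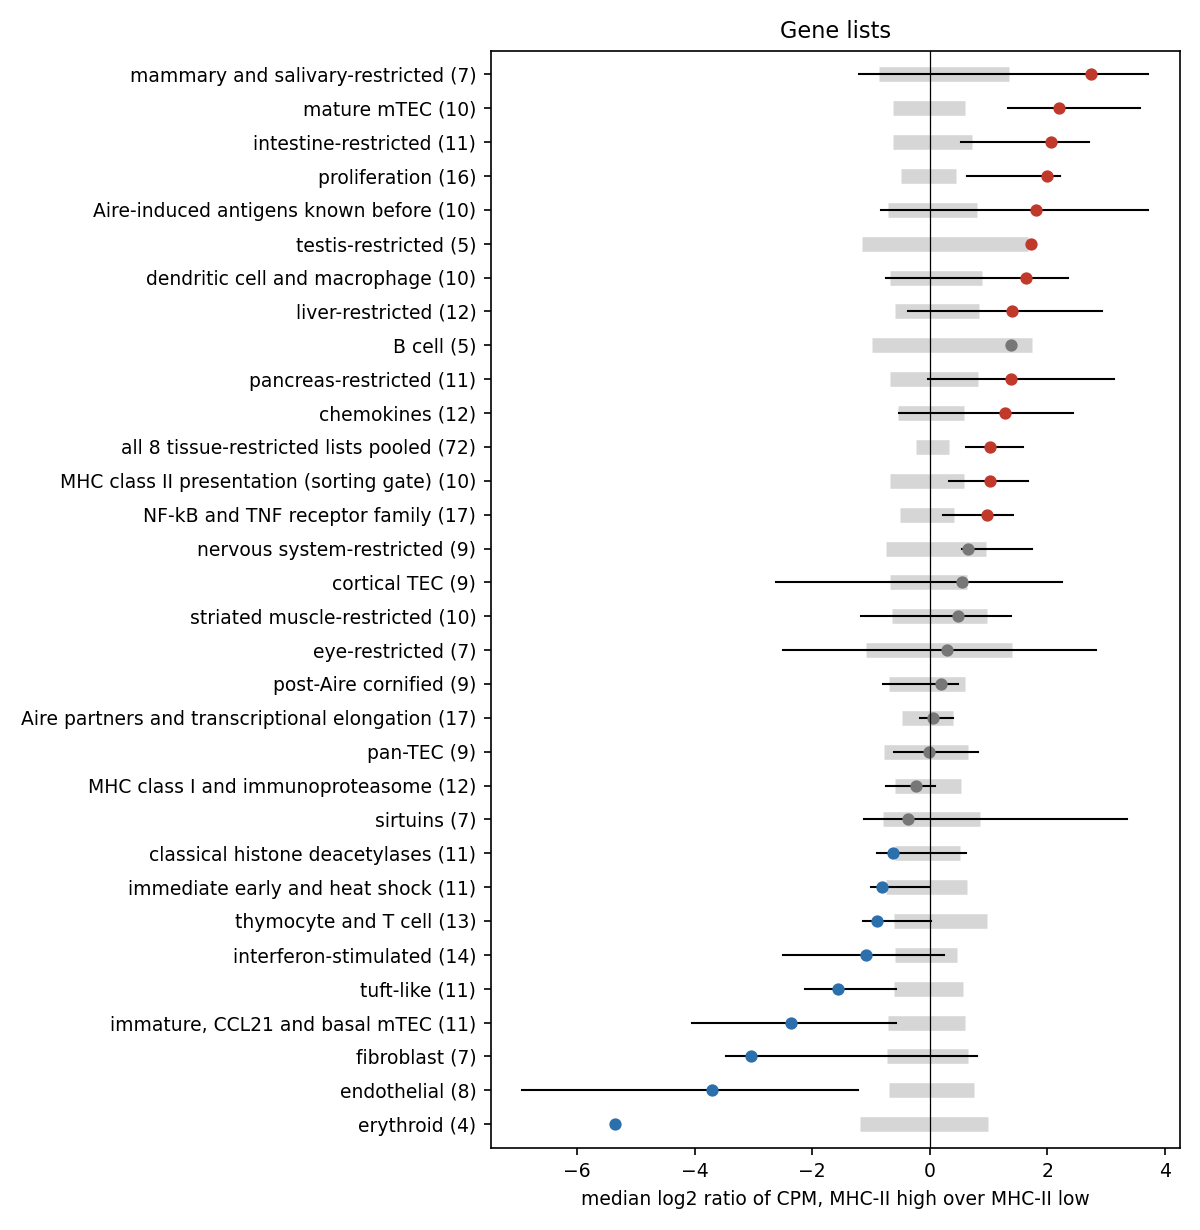
The x axis is the median log2 ratio of CPM in the MHC-II high over the MHC-II low library for each gene list on the y axis, with the number of members past the minimum in brackets; points are medians, black lines their 95% order-statistic intervals (drawn for lists with at least 6 members) and grey bars the central 95% of 10000 random lists matched on expression. Lists run from erythroid (−5.35) to mammary and salivary-restricted (2.74), and red and blue points lie above and below the grey bar.

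The last question was whether the MHC-II high library held reads on more genes. At equal depth, 21905 genes (21877 to 21934 over 100 draws) had at least 1 read in the high library against 22705 in the low library, a mean difference of −799.97 genes. The difference was −1412.22 for genes with at least 5 reads and −1289.44 for those with at least 10. Unthinned, the high library had 22259. Of 84 measured tissue-restricted genes, 83 had at least 1 read in each unthinned library.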

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

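Both values below were looked at only after the gap in each table had been seen. In the MHC-II high table, 51 genes that the low table does not list together held 205384 reads. This sum does not show whether these genes had reads in the low library. They stood on consecutive lines. The most abundant were the epidermal gene Dmkn at 144 CPM, the lipoprotein receptor gene Lsr at 125 CPM, the NF-kB regulator gene Nfkbid at 120 CPM, Cox6b1 at 108 CPM and the cornified-cell gene Sbsn at 102 CPM. In the MHC-II low table, 23 genes that the high table does not list held 3206 reads, led by the zinc finger genes Zfp180 at 39.8 CPM and Zfp235 at 13.4 CPM. No ratio can be given for these genes, and they entered no comparison except where missing accessions were set to 0.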

How the results depend on the processing

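The RPKM read totals, counting genes with identical reads once and thinning to the TMM-scaled total were tried only after the data had been seen, and the other alternatives were planned. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Of 50 alternative values for the main counts, Sirt1, the pooled tissue lists and the genes detected, 38 stayed near the reported value and 12 moved. Of those for single genes and lists, 2982 stayed, 750 moved and 8 reversed. Only genes beyond 2-fold, list medians outside the central 95% of random lists and summed ratios could count as reversed. Over all these values, 90 changed sign with the RPKM read totals, 25 with unscaled totals and 6 with upper quartile scaling. The numbers higher and lower were 3973 and 3562 at 1.5-fold and 853 and 571 at 4-fold. A minimum of 5 CPM left 1652 higher, fewer genes being compared. No minimum brought in more genes and gave 2837 higher and 3822 lower, so those added beyond 2-fold were mostly lower. Unscaled totals gave Sirt1 a log2 ratio of 3.64 and the pooled lists a summed one of 1.27. The RPKM read totals gave 7232 higher, 471 lower, 4.36 for Sirt1 and 1.98 for the pooled lists. They turned the medians of histone deacetylases (0.38), immediate early genes (0.19) and T cell genes (0.11) and the sum of Aire-independent genes (0.053) positive, as they move the median of all genes by 1.01. With them 16 of 16 cell cycle, 15 of 17 NF-kB and TNF receptor, 9 of 17 Aire partner, 9 of 10 MHC class II, 8 of 8 nervous system, 7 of 9 striated muscle and 5 of 9 cornified-cell genes were higher. Leaving out the member with the most reads turned the summed log2 ratios of Aire-induced (−0.34), Aire-independent (2.42), eye (−0.079) and mammary and salivary genes (−0.76). Depth limits genes with few reads in 1 library, such as Sult1e1 with 1 read in the low one.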

Other observations

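The gene families in the next paragraph, and all tests in this part except the 5 said to have been written in advance, were chosen after the values they concern had been seen.

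Of 14 gene families grouped by name, some went with the tissue-restricted lists and others did not. Reads summed over 30 genes of alpha-defensins, antimicrobial peptides of Paneth cells, were higher in the MHC-II high library by 3.12 on the log2 scale (interval 2.94 to 3.30). Only 13 of them passed the minimum, all through the high library, so their single calls are not counted, and as near-identical copies their single values are uncertain. Defa23 and Defa31 held the same reads, as did Defa32 and Defa33. The sum may therefore count reads more than once, and its interval may be too narrow. Of 26 interleukin genes, 15 were higher and 5 lower. Most of the higher ones, such as Il22 and Il9 at 0.473 and 0.276 CPM in the low library, passed the minimum only through the high library. The count therefore carries the same limit, and reads summed over all 32 interleukin genes gave a log2 ratio of 0.69 (interval 0.67 to 0.71). Il13 was at 127 against 5.28 CPM, Il12a was 22.1-fold higher and Il23a 6.52-fold, while the inflammatory cytokine gene Il6 was 9.37-fold and Il34 5.22-fold higher in the low library. Of 11 Ceacam adhesion genes 6 were higher and 0 lower, with Ceacam15 16.1-fold and Ceacam18 12.8-fold higher. Among those 6, Ceacam9, Ceacam11 and Ceacam12 passed the minimum only through the high library. Reads summed over all 16 Ceacam genes gave a log2 ratio of 0.85 (interval 0.81 to 0.89). Over 20 genes for the major urinary proteins, which the liver secretes, the summed log2 ratio was 2.18 (2.02 to 2.34), with 5 past the minimum, again only through the high library. Other families split or went the other way. Of 48 keratin genes 19 were higher and 8 lower, with a median of 1.05 but a summed log2 ratio of −1.36, and of 53 serpin genes 15 were higher and 9 lower. Some of these genes passed the minimum through 1 library only, such as Krt33a and Serpinb9b among the higher and Serpina1f among the lower. Of 43 collagen genes 3 were higher and 13 lower, and of 362 zinc finger genes 21 were higher and 51 lower, or 38 and 35 with unscaled totals. Of 75 cytosolic ribosomal protein genes 16 were lower and 0 higher, but 0 were lower with unscaled or RPKM read totals. Their median was −0.80, or −0.51 and 0.20 with those totals, and complex I genes had a median of −0.62 that was 0.38 with the RPKM read totals.

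Sirt1 was higher in the MHC-II high library by 3.36 on the log2 scale. Reads of neighbouring genes counted on Sirt1 are argued against by Herc4 and Dnajc12, the higher of which had a log2 ratio of 0.41. Scaling between the libraries is argued against by the lowest value over the scalings, 3.36. The difference may belong to the stage sorted by MHC-II, but with 1 library per group the stage cannot be told apart from any other difference between the 2 libraries.

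Endothelial, fibroblast and erythroid genes were higher in the MHC-II low library. A lower share of epithelial cells raising every other cell type alike is argued against, as the median of dendritic cell and macrophage genes lay 5.35 above that of endothelial genes on the log2 scale, with intervals that do not meet. This speaks only against a rise of all alike. The gate on MHC-II may itself part other cell types, so a lower share of epithelial cells stays open. Scaling is argued against as well, since the endothelial median was at most −2.70 over the scalings. RNA of endothelial cells and fibroblasts, which a sort for epithelium would remove, is a candidate source in the low library, as 39 further marker genes listed before their values were looked at, a test written in advance, had a median of −1.99 and 28 of them were lower and 0 higher. Of the listed markers 0 are in another list, all 8 endothelial and 7 fibroblast genes also had reads in the high library, the most abundant of these in the low library were Dcn (535 CPM), Col3a1 (208 CPM) and Pecam1 (163 CPM), and whether the sorted stage differs in these genes stays open.

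Tissue-restricted genes were higher in the MHC-II high library, with a pooled median log2 ratio of 1.03. Gene length is argued against by a test written in advance, in which the median lay at percentile 100 of lists matched on expression and length. Depth acts alike on genes of the same expression, and the median lay at percentile 100 of lists matched on expression alone. This argues against depth, but it is the comparison already given in the Results and no separate check. It was taken up as a test of depth only after the equal-depth count was known. Reg3g, Csn2 and Syt1 hold 55.8% of the reads of the pooled lists in the high library. Without them the summed log2 ratio fell from 0.98 to 0.43 (interval 0.41 to 0.44). Much of the summed difference therefore rests on these 3 genes, and a few genes are argued against only as its whole source. The pooled median was 0.97 without them, but a median depends little on a few members. The test written in advance left out Reg3g alone and gave 0.98. It decides nothing, as the log2 ratio of Reg3g itself is 0.98. The other test written in advance took no more genes with at least 1 read in the high library at equal depth as a sign of depth, and the difference was −799.97, but this count does not decide on depth, as 83 of 84 measured members had a read in each library, nor on wider transcription in the high library, as the low library led at minimums of 5 and 10 reads too (−1412.22 and −1289.44) but not at 1 CPM without thinning (17264 genes in the high against 17142), so wider transcription and, with 1 library per group, the sorted stage stay open. The gene count itself may be set by reads spread over all genes in proportion to length in the low library, as over 5509 genes under the minimum reads followed length more closely there, by 0.22 in Spearman's rho across genes (bootstrap interval 0.20 to 0.25), a test written before rho was computed but after the equal-depth count and the reads of olfactory receptors had been seen.

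Of 1116 olfactory receptor genes, 1057 (94.7%) had a read in the low library and 598 (53.6%) in 1 draw of the high library at equal depth.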
